A study of Mus musculus with 12 samples.

How the data were processed

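Messenger RNA was measured on 12 single-colour Agilent whole mouse genome arrays of design 014868, with 3 arrays in each of 4 groups: adult lung, adult mammary, reprogrammed lung and reprogrammed mammary cells. Per the labels, total RNA was labelled with Cy3 after low-input linear amplification. The adult cells came from adult female mice, whose organs were dissociated with trypsin and collagenase and whose cells were purified by repeated washes and low-speed centrifugation, with no cell sort stated. The labels do not say whether the organ name of a reprogrammed sample is that of the donor cells or of the tissue that formed. They also do not say whether the arrays of a group come from separate animals, so replicates are counted as arrays.

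The deposited scanner files hold, per the file headers, the output of Agilent Feature Extraction 10.5.1.1, whereas the submitters' notes name version 10.1. Per the file headers, the processed signal of each spot is an intensity on the scanner's linear scale after background subtraction and spatial detrending within an array, with small values replaced by the program's surrogate, and no scaling between arrays. The raw median pixel signal and the local background in the deposited files are intensities as well. The authors' series matrix holds log2 values. From the values, its columns rank as the raw median signal does (Spearman correlation of at least 0.999998 on each array), with no background subtracted. Their medians lie between 6.78 and 6.79 on all 12 arrays, so the arrays were brought to a common level. Equal medians do not tell quantile normalization from other scaling between arrays. The method behind these log2 values is not given in the sources used here.

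Each file holds 43379 non-control spots for 41174 distinct probes, of which 245 have 10 spots each. Spots of a probe were averaged, and spots marked as outliers (91 to 280 per array) were left out, so that 308 of the tested features lacked a value on some array. No spot was saturated. Probes were named by matching the accession in the array design to a reference table of mouse transcripts, which gave a symbol to 24844 probes (17178 distinct symbols). The other 16330 probes kept their accession and were tested without a gene name. Probe positions on the genome were not used here. Where several probes carried a symbol, the probe with the highest mean over the arrays stood for the gene, which left 32678 features.

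The main values were log2 of the processed signal minus the array's 75th percentile, so a level of 0 is the 75th percentile of the array. A feature was tested if its probe was well above background, by the scanner program's own mark, on all 3 arrays of at least 1 group. This kept 24504 features, of which 14749 carry a gene symbol, and 20731 were above background on all arrays. The signal at the 75th percentile ran from 293.8 to 608.5, against negative-control medians of 18 to 23. The number of arrays, 3 per group, limits the precision of every comparison.

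Differences were fitted with limma 3.58.1 in R 4.3.3: a linear model with a mean for each group over all 12 arrays, moderated variances without a trend (8 residual and 2.37 prior degrees of freedom), and two-sided p adjusted by the Benjamini-Hochberg method within each comparison at 0.05. The comparisons were adult lung minus adult mammary, each reprogrammed group minus the adult group of the same organ name, each reprogrammed group minus the other adult group, reprogrammed lung minus reprogrammed mammary, and the organ difference of the reprogrammed minus adult change. Standard errors are the model's moderated ones. A fold change whose lower group was not above background on any array is given as a bound, computed against the lowest level marked above background on each of those arrays, and written "at least". Where the lower group was above background on 1 or 2 arrays, its other arrays were set to that level in the same way.

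For 33 gene lists written from textbook knowledge, limma's camera compared each list with all other features, with a preset inter-gene correlation of 0.01 and adjustment over the 33 lists. The same test with an estimated correlation, and limma's fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run beside it. List tests used the 24196 features with a value on every array. For each list, members past the threshold were counted with p adjusted over all features and with p adjusted over the list alone. A position between the adult groups was computed for each array as the median, over the genes that differed at least 2-fold between the adult groups, of the share of the way from the adult mammary mean (0) to the adult lung mean (1). For an adult array, that array was left out of the choice of genes and of the means. Positions were compared with exact two-sided permutation tests. Correlations between arrays are Pearson's r across features, which are not independent replicates.

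Genes were named by a fixed rule. In each of the comparisons between the adult groups, of each reprogrammed group with its adult group, and between the reprogrammed groups, these were the 5 genes per direction with the largest change past the threshold that were above background on all 3 arrays of the higher group, then the 2 members that changed most in the list's direction from each of up to 10 lists with the smallest camera p, and 12 marker genes. For the organ difference, only the 5 genes per direction were named. Further list members were taken in order of change. The groups, comparisons, gene lists, naming rule, thresholds and most alternatives were chosen before the data were examined.

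The alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' series matrix values, no filter on dim probes, a filter requiring all 12 arrays above background, the mean of a gene's probes, moderated variances with a trend, only the groups compared in the fit, a replicate block (the replicate number of the labels as a fixed block), the slide as a fixed and as a random block, changes within a slide, leaving out each array in turn, a threshold of at least 2-fold, and a position from the lung and mammary gene lists. Normexp took the raw median signal, since the files give no raw mean signal. That substitution, a fit without the 2 arrays with the most probes above background, and limma's array weights were chosen after seeing the data. The 12 arrays lie on 5 slides with 1 scan date. Slide 1 holds adult lung replicate 1, adult mammary replicate 2 and reprogrammed lung replicate 3. Slide 2 holds adult mammary replicate 1 and reprogrammed mammary replicate 1. Slide 3 holds adult lung replicate 3 and reprogrammed lung replicate 1. Slide 4 holds adult mammary replicate 4 and reprogrammed mammary replicate 3. Slide 5 holds adult lung replicate 2, reprogrammed lung replicate 4 and reprogrammed mammary replicate 2.

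The fit was tested on simulated data with the same 24196 features and 3 arrays per group. It recovered 22 to 26 of 100 features changed 2-fold and 56 to 63 of 100 changed 4-fold, with 2 to 8 false calls per comparison. It called the simulated shifted list and 0 other lists. Noise was drawn independently for each gene, with the same spread on every array. The list result therefore does not show how camera behaves under the correlation between real genes. Recovery may be lower where fewer features change, since the adjusted threshold is then stricter. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.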

Results

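Gene expression was measured in cells of adult mouse lung and mammary gland and in cells named reprogrammed lung and reprogrammed mammary, in a study of how stroma redirects adult cells to rebuild an organ. There were 12 arrays, 3 per group. Adult lung and reprogrammed mammary have replicates 1, 2 and 3, adult mammary has replicates 1, 2 and 4, and reprogrammed lung has replicates 1, 3 and 4. Each array carried 43379 non-control spots. Probes well above background made up 71.8% to 77.5% of the array on 10 arrays, 89.1% on adult mammary replicate 4 and 91.1% on reprogrammed lung replicate 1. On these 2 arrays the log2 span from the 10th to the 90th percentile of signal was also narrower, at 7.11 and 6.10 against 8.46 to 9.13 on the other 10.

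Adult lung stood apart from the other 3 groups. Reprogrammed lung arrays lay near the adult mammary arrays, not near adult lung. On the scale from the adult mammary mean (0) to the adult lung mean (1), over 4728 genes, adult lung arrays lay at 0.977 ± 0.0375 (SD, n = 3) and adult mammary arrays at 0.0637 ± 0.0644 (SD, n = 3). Reprogrammed lung arrays lay at 0.157 ± 0.0990 (SD, n = 3) and reprogrammed mammary arrays at 0.0728 ± 0.00937 (SD, n = 3). Reprogrammed lung replicate 1 lay at 0.266, replicate 3 at 0.0718 and replicate 4 at 0.134. The exact permutation p was 0.1 for reprogrammed lung against adult lung, 0.2 for reprogrammed lung against reprogrammed mammary, 0.3 for reprogrammed lung against adult mammary and 0.9 for reprogrammed mammary against adult mammary, where 0.1 is the smallest p that 3 against 3 arrays allow. Across features, reprogrammed lung arrays correlated with the adult mammary mean at r = 0.939 ± 0.0484 (SD, n = 3) and with the adult lung mean at 0.864, and reprogrammed mammary arrays at 0.972 and 0.876. Adult lung arrays correlated with their own group at 0.984 and adult mammary arrays at 0.968.

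**Figure D1:**
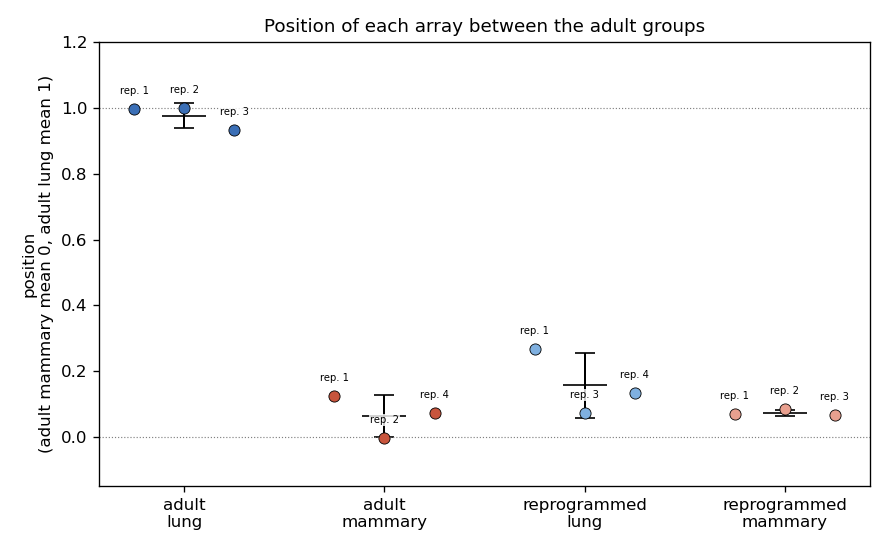
Position of each array (points, labelled by replicate) on a scale where the adult mammary mean is 0 and the adult lung mean is 1, by group, with the group mean (bar) and SD. The 3 reprogrammed lung arrays lie between 0.0718 and 0.266, and the 3 adult lung arrays near 1.

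The first comparison, adult lung against adult mammary, shows what distinguishes the source organs. Genes of the lung's gas-exchange and airway epithelium were far higher in adult lung, and milk protein and hormone-receptor genes of the mammary gland far higher in adult mammary. Sftpc, surfactant protein C of alveolar type II cells, was 1485-fold higher in lung (log2 10.54 ± 0.54 SE, adjusted p = 4.79e-06, n = 2 adult lung and 3 adult mammary arrays, since its spots on adult lung replicate 2 were marked as outliers). Scgb1a1, the secretoglobin of airway club cells, was 1154-fold higher (log2 10.17 ± 0.74 SE, adjusted p = 1.53e-05, n = 3 per group). Wfdc18, a secreted protease-inhibitor family member, was at least 1090-fold higher in mammary (log2 -10.24 ± 0.79 SE, adjusted p = 2.09e-05), and Csn3, kappa casein of milk, at least 342-fold higher (log2 -9.86 ± 0.84 SE, adjusted p = 3.46e-05), with 2 and 1 of the 3 adult lung arrays above background.

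Lung epithelial genes rose together. Of 16 measured alveolar type II genes, 14 were higher in lung and 0 lower (14 higher and 1 lower when adjusted over the list alone), with a median log2 of 4.73 and a camera adjusted p of 9.97e-09. Besides Sftpc, which lacks a value on 1 array and was left out of the list test, these included Sftpa1, a surfactant protein (log2 9.22, at least 255-fold), Nkx2-1, the transcription factor of lung and thyroid identity (log2 8.73, at least 124-fold), Slc34a2, a phosphate transporter (7.33), and Sftpb, surfactant protein B (6.82). Of 15 alveolar type I genes, 13 were higher and 0 lower (14 and 0 when adjusted over the list alone), with a median of 2.92 and adjusted p = 5.01e-13. Akap5, a kinase anchoring protein, reached log2 7.66 (at least 189-fold), Ager, the receptor for advanced glycation end products that marks these cells, 7.30 (157-fold), Col4a3, a basement membrane collagen, 5.77, and Hopx, a homeodomain protein, 5.00. Of 15 airway secretory genes, 11 were higher and 2 lower by both counts, with a median of 4.65 and adjusted p = 1.28e-06. Among them were Bpifa1, a secreted airway defence protein (log2 7.91, at least 83.9-fold), Cyp2f2, a club cell cytochrome (6.22), and Scgb3a1, a secretoglobin (5.99). Chia1, an acidic chitinase, was at least 215-fold higher (log2 9.91). Another tested probe gave 10.62 for Sftpa1, 4.75 for Col4a3 and 7.35 for Chia1.

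Mammary genes were lower in lung. Of 17 milk and alveolar luminal genes, 10 were lower in lung and 0 higher (12 and 0 when adjusted over the list alone), with a median log2 of -3.68 (-3.45 with the 7 members that were dim in lung at their bound) and adjusted p = 4.96e-05, against adjusted p = 0.439 with an estimated correlation. The caseins Csn1s1 (log2 -9.42) and Csn1s2a (-8.90) were at least 149-fold and at least 115-fold higher in mammary, Btn1a1, a milk fat globule protein, at least 49.4-fold (-7.73), and Csn2, beta casein, at least 28.0-fold (-6.99, adjusted p = 0.0291). Leaving out 1 array moved Csn1s1 to between -8.28 and -10.91 and Csn1s2a to between -7.55 and -10.16. Elf5, the alveolar luminal transcription factor, stood at -3.68. The call for Csn2 was lost without any 1 of the adult lung arrays or without adult mammary replicate 2 or 4 (log2 -5.62 to -7.14, adjusted p = 0.0699 to 0.11), with the authors' values (adjusted p = 0.0989) and with the slide as a fixed block (0.11). With the slide as a fixed block Elf5 (-3.23, adjusted p = 0.0655) was not past the threshold either. The list call was lost over features above background on all arrays (-1.62, adjusted p = 0.191). With normexp background correction the calls for Csn1s2a (-4.03), Csn2 (-2.44) and Adipoq (-0.67) were lost. Of 15 hormone-sensing luminal genes, 11 were lower in lung and 1 higher (11 and 2 when adjusted over the list alone), with a median of -3.30 and adjusted p = 0.000108, but adjusted p = 0.369 with an estimated correlation. They included Calca, the calcitonin gene (log2 -8.16, at least 108-fold), Prlr, the prolactin receptor (-6.90), Cited1, a transcriptional coregulator (-6.51), and Esr1, the oestrogen receptor (-5.11, at least 15.6-fold). Of 17 basal and myoepithelial genes, 10 were lower and 0 higher (11 and 0 when adjusted over the list alone), with a median of -1.70 and adjusted p = 0.000291, and adjusted p = 0.426 with an estimated correlation. Wnt10a, a Wnt ligand, stood at log2 -5.22 (at least 14.5-fold, and -6.70 without adult lung replicate 3), Krt17, a basal keratin, at -4.12, Trp63, the basal cell transcription factor, at -4.04, and Krt14, a basal keratin, at -3.40, though the call for Krt14 was lost with the slide as a fixed block (-2.87, adjusted p = 0.113). Another tested probe gave -11.56 for Wfdc18, -3.17 for Calca, -4.38 for Esr1 and -3.34 for Trp63. Fgb, the fibrinogen beta chain, was at least 221-fold higher in mammary (log2 -9.10).

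General epithelial genes were lower in adult lung and endothelial genes higher. Of 21 pan-epithelial genes, 15 were lower and 0 higher (17 and 0 when adjusted over the list alone), with a median of -2.08 and adjusted p = 3.54e-07, but adjusted p = 0.426 with an estimated correlation. Cldn4, a tight junction claudin, stood at log2 -5.14, Epcam, the epithelial adhesion molecule, at -3.82, Krt18 at -3.47 and Krt19 at -3.39, with Epcam not past the threshold with the slide as a fixed block (-3.16, adjusted p = 0.0523). Of 16 endothelial genes, 14 were higher and 0 lower by both counts, with a median of 2.37 and adjusted p = 3.91e-10, and adjusted p = 0.369 with an estimated correlation. Ramp2, a receptor-modifying protein of vessels, rose by log2 3.42, Cldn5, the endothelial claudin, by 3.39, Egfl7 by 3.24 and Kdr, the receptor for vascular endothelial growth factor, by 2.79. Of 18 ciliated cell genes, 7 were higher and 2 lower (9 and 2 when adjusted over the list alone), with a median of 1.22 and adjusted p = 0.00357, and adjusted p = 0.426 with an estimated correlation. Dynlrb2, a dynein light chain, stood at 4.57 and Dnali1 at 3.06. Foxj1, the master factor of cilia, differed by 1.98 without passing the test (adjusted p = 0.136), but passed it with the authors' values (adjusted p = 0.0115), normexp (0.0292), the slide as a fixed block (0.0251), array weights (0.029) and without reprogrammed lung replicate 1 and adult mammary replicate 4 together (0.0426).

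Of 37 ribosomal protein genes, 35 were lower in lung and 0 higher by both counts, with a median of -1.03 and adjusted p = 8.32e-14, and adjusted p = 0.114 with an estimated correlation. Rpl14 stood at -1.86 and Rpl32 at -1.77. Of 27 cell cycle genes, 5 were lower and 0 higher by both counts, with a median of -1.45 and adjusted p = 0.00206, against adjusted p = 0.795 with an estimated correlation. The array median was -0.87 on adult mammary replicate 1, within the adult lung range of -1.26 to -0.26, and 1.22 and 1.73 on replicates 2 and 4, so the list difference rests on 2 of the mammary arrays. It was -2.13 without replicate 1 and -0.88 without replicate 4. Mcm6 (log2 -2.30) and Mcm5 (-2.10), subunits of the replicative helicase, passed the test. Neither did without adult lung replicate 1 or 2 or adult mammary replicate 2 or 4 (Mcm6 -1.95 to -2.43, adjusted p = 0.0536 to 0.0907), nor did Mcm5 without adult lung replicate 3. The replicate block ended both calls (Mcm6 -2.37, adjusted p = 0.0642, and Mcm5 -2.01, 0.0945), and the slide as a fixed block (-2.97, 0.0602) and normexp (-1.47, 0.0535) ended that of Mcm5. Of 18 Hox genes of paralog groups 6 to 13, which mark posterior body position, 7 were lower and 0 higher (7 and 1 when adjusted over the list alone), with a median of -0.30, a mean of -1.39 and adjusted p = 0.0166, and adjusted p = 0.66 with an estimated correlation. Hoxc10 was at least 82.1-fold lower in lung (log2 -8.22) and Hoxd9 lower by log2 -4.11, but another tested probe gave -3.49 for Hoxc10 and -0.14 for Hoxd9. The call for this list was lost without adult mammary replicate 1 (median -0.15, adjusted p = 0.064), with the replicate block (-0.25, 0.0557) and with only the groups compared in the fit (0.0545), and its median was above 0 with normexp background correction (0.29), over genes above background on all arrays (0.046) and within slide 1 (0.40).

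The other 21 lists were not called. Their medians were -1.04 for fibroblast, -0.71 for adipocyte, -0.13 for macrophage, 1.59 for T and NK cell, 1.39 for B cell, 0.46 for neutrophil, 1.59 for erythroid, 0.76 for skeletal muscle and 0.26 for kidney tubule genes. They were -0.71 for cornified and squamous, 0.39 for pluripotency, 0.62 for embryonic lung epithelium, 0.06 for embryonic mammary bud and 0.80 for paralog group 1 to 5 Hox genes. They were -0.52 for immediate-early and dissociation, -0.11 for interferon-response, -0.02 for fatty acid and triglyceride synthesis, 0.11 for cholesterol synthesis, -0.53 for matrix remodelling, -0.25 for epithelial-mesenchymal transition and -0.61 for hypoxia and glycolysis genes. Adjusted p over these lists ran from 0.0696 to 0.943. The mean and test had the opposite sign to the median for macrophage and fatty acid synthesis genes (means 0.18 and 0.15), the mean alone for pluripotency genes (-0.30) and cornified genes (0.11), and the mean and test for mammary bud genes (-0.54). Adipoq, the adipocyte hormone adiponectin, was lower in lung (log2 -3.31, at least 8.71-fold, adjusted p = 0.00346), and Fabp4, a fatty acid binding protein of fat and endothelium, stood at -4.74 (-6.22 to -4.44 over its 3 probes). Vim, vimentin of mesenchymal cells, differed by 0.08 (adjusted p = 0.866). Without adult mammary replicate 4, T and NK cell (3.10, adjusted p = 0.00631), adipocyte (-1.05, 0.015) and immediate-early genes (-0.74, 0.0104) were called, without adult lung replicate 1 erythroid genes (2.01, 0.0448), and without adult mammary replicate 1 group 1 to 5 Hox genes (0.83, 0.0296). Without reprogrammed lung replicate 4 adipocyte (adjusted p = 0.0296) and immediate-early genes (0.0391) were called, and without reprogrammed mammary replicate 2 T and NK cell genes (0.0497).

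In all, 3071 features were higher and 3907 lower in adult lung, 2146 and 2582 of them at least 2-fold. The share that was higher was 44.0%, against 61.1% with normexp background correction, which moved the median of all features from 0.00 to 0.30. Within slide 1, which holds 1 adult lung and 1 adult mammary array, list medians were 5.12 for alveolar type II, 2.94 for type I, 3.83 for airway secretory, -4.50 for milk, -2.38 for pan-epithelial and 2.20 for endothelial genes. With the slide as a fixed block 2702 features passed.

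**Figure D2:**
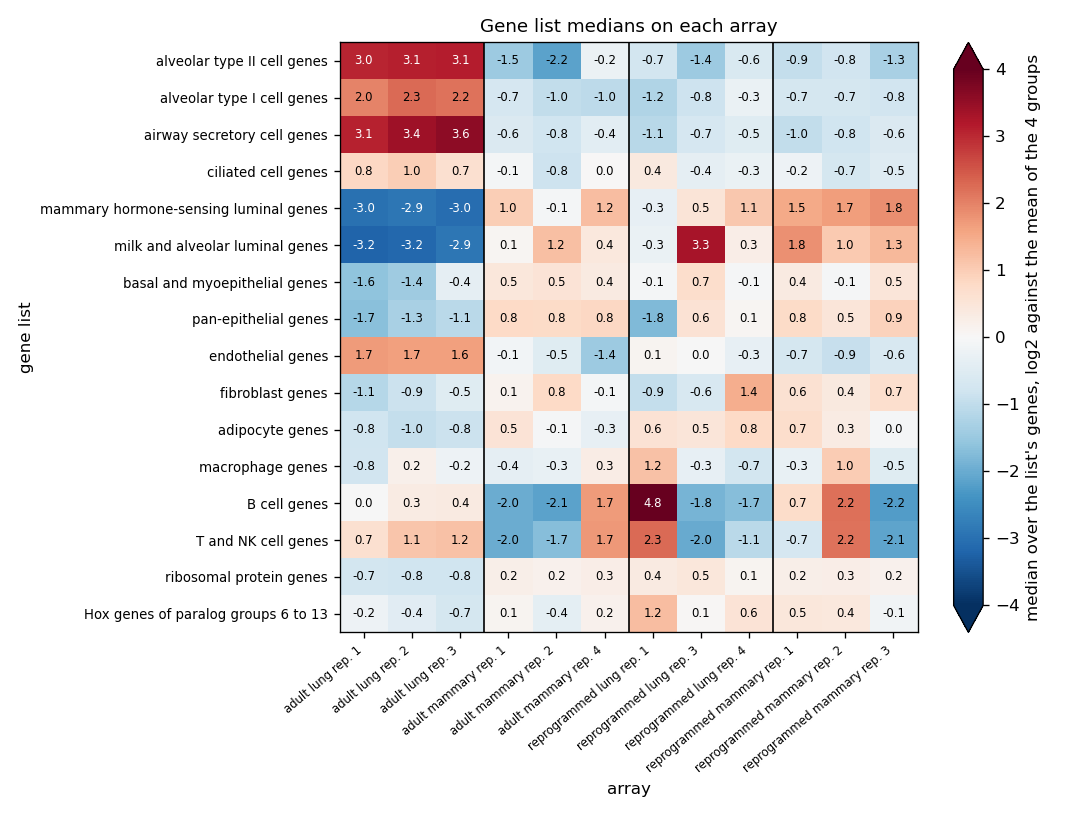
Median log2 level of 16 gene lists (vertical) on each of the 12 arrays (horizontal), against the mean of the 4 groups. Colour runs from blue (lower) to red (higher). Lung epithelial and endothelial genes are high on the 3 adult lung arrays, and milk and hormone-sensing genes are lower there than on each of the other 9 arrays.

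The comparison of reprogrammed lung with adult lung asks how far cells that carry the name lung after reprogramming share the adult lung's expression. Lung epithelial genes fell and mammary genes rose. Sftpc was 649.7-fold lower (log2 -9.34 ± 0.54 SE, adjusted p = 9.76e-06, n = 2 adult lung and 3 reprogrammed lung arrays) and Scgb1a1 681-fold lower (log2 -9.41 ± 0.74 SE, adjusted p = 2.68e-05, n = 3 per group). Nkx2-1 was at least 109-fold lower (log2 -8.29) and was above background on no reprogrammed lung array. Wfdc18 rose at least 920-fold (log2 9.99 ± 0.79 SE, adjusted p = 2.74e-05) and Csn3 at least 332-fold (log2 9.81 ± 0.84 SE, adjusted p = 4.25e-05). Leaving out 1 array moved Wfdc18 to between 8.91 and 10.94 and Csn3 to between 9.21 and 10.75.

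Of 16 alveolar type II genes, 14 fell and 1 rose by both counts, with a median of -3.99 and adjusted p = 1.44e-09. Sftpa1 stood at log2 -7.14 (at least 83.3-fold), Slc34a2 at -6.94 and Sftpb at -6.40, while Slc27a2, a fatty acid transporter, rose by 2.33. Of 15 alveolar type I genes, 13 fell and 0 rose (14 and 0 when adjusted over the list alone), with a median of -2.71 and adjusted p = 8.68e-16, led by Akap5 (-7.61) and Ager (-7.28). Of 15 airway secretory genes, 11 fell and 0 rose (12 and 1 when adjusted over the list alone), with a median of -3.46 and adjusted p = 1.58e-08. Cyp2f2 stood at -6.89, Aldh1a7, an aldehyde dehydrogenase, at -6.34 and Cbr2, a carbonyl reductase, at -5.19. Chia1 was at least 189-fold lower (log2 -9.29). Another tested probe gave -9.41 for Sftpa1, -7.01 for Chia1 and 11.30 for Wfdc18. Of 18 ciliated cell genes, 6 fell and 1 rose by both counts, with a median of -0.72 and adjusted p = 0.00152, and adjusted p = 0.379 with an estimated correlation. Dynlrb2 stood at -3.76 and Rsph1, a radial spoke protein, at -2.59, though the call for Rsph1 was lost without any 1 of the adult lung arrays or without reprogrammed lung replicate 3 or 4. Foxj1 differed by -1.89 (adjusted p = 0.175) without passing the test, but passed it with the authors' values (adjusted p = 0.00596), quantile normalization (just under 0.05), the slide as a fixed block (0.0353), array weights (0.0391) and without reprogrammed lung replicate 1 and adult mammary replicate 4 together (0.0448).

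Of 17 milk and alveolar luminal genes, 12 rose and 0 fell (14 and 0 when adjusted over the list alone), with a median of 4.59 (3.57 with 7 members at their bound) and adjusted p = 9.41e-06, and adjusted p = 0.392 with an estimated correlation. Csn1s2a rose at least 134-fold (log2 9.13), Csn1s1 at least 87.9-fold (8.66) and Btn1a1 at least 26.7-fold (6.84). These rises were uneven. The SD over the reprogrammed lung arrays was 4.02 for Csn1s2a and 3.41 for Csn1s1, their rises were 6.85 and 6.70 without replicate 3, and the list's array medians were -0.27, 3.29 and 0.27 on replicates 1, 3 and 4. Glycam1, a milk mucin that lymph node vessels also make, rose at least 136-fold (9.29, adjusted p = 0.0124) with an SD of 4.22 over the reprogrammed lung arrays. Its rise was 7.13 without replicate 1, the array with the highest B cell list median (2.85), and 11.35 without replicate 4. With the replicate block Glycam1 was not past the threshold (9.64, adjusted p = 0.0601). Csn2 differed by 5.98 (at least 13.9-fold, adjusted p = 0.0625), and passed without reprogrammed lung replicate 4 (7.83, adjusted p = 0.021), with a trend in limma's variance (0.0498) and with array weights (0.00742). Elf5 rose by 2.63, but not past the threshold with only the groups compared in the fit (adjusted p = 0.0675). The list call was lost over features above background on all arrays (2.35, adjusted p = 0.0766). With normexp background correction the calls for Csn1s2a (log2 4.30), Csn1s1 (3.77), Glycam1 (4.41), Esr1 (1.098), Elf5 (1.18) and Adipoq (0.71) were lost. Of 15 hormone-sensing luminal genes, 9 rose and 1 fell (12 and 1 when adjusted over the list alone), with a median of 2.97 and adjusted p = 0.000896, and adjusted p = 0.392 with an estimated correlation. Ptn, the growth factor pleiotrophin, rose by 6.90, Prlr by 5.40 and Esr1 at least 11.4-fold (4.65, or 4.02 with another tested probe). Of 17 basal and myoepithelial genes, 8 rose and 0 fell (9 and 0 when adjusted over the list alone), with a median of 1.35 and adjusted p = 0.0113, and adjusted p = 0.649 with an estimated correlation, among them Wnt10a (3.64, at least 4.85-fold), Trp63 (3.41, or 2.52 with another probe) and Id4 (3.03). Without reprogrammed lung replicate 3 this list's adjusted p was 0.0776 (median 0.90). Krt14 differed by 1.35 (adjusted p = 0.181), and passed without reprogrammed lung replicate 1 (1.95, adjusted p = 0.046).

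Of 18 Hox genes of paralog groups 6 to 13, 8 rose and 0 fell by both counts, with a median of 0.74 and adjusted p = 2.1e-05, and adjusted p = 0.375 with an estimated correlation. Hoxc10 stood at log2 8.58 (at least 105-fold) and Hoxd9 at 5.19, but another tested probe gave 3.78 for Hoxc10 and 0.96 for Hoxd9, so the size of both is open. Of 37 ribosomal protein genes, 35 rose and 0 fell (37 and 0 when adjusted over the list alone), with a median of 1.08 and adjusted p = 1.33e-15, and adjusted p = 0.0887 with an estimated correlation, such as Rpl32 (1.68) and Rpl10a (1.62). Of 16 endothelial genes, 12 fell and 0 rose (13 and 0 when adjusted over the list alone), with a median of -1.83 and adjusted p = 5.55e-09, and adjusted p = 0.379 with an estimated correlation, such as Cldn5 (-3.14) and Tek, the angiopoietin receptor (-2.54). Of the pan-epithelial genes, 9 rose and 0 fell (10 and 0 when adjusted over the list alone), with a median of 1.03 and adjusted p = 0.00437, and adjusted p = 0.765 with an estimated correlation. Cldn4 rose by 3.38 and Epcam by 2.69, but with only the groups compared in the fit neither was past the threshold (adjusted p = 0.0537 and 0.0811). Reprogrammed lung replicate 1 lay at -1.76 for this list, below the adult lung arrays (-1.66 to -1.09), and replicates 3 and 4 at 0.59 and 0.09. Epcam stood at 1.58 on replicate 1 and at 4.65 and 4.33 on the other 2, against 0.56 to 1.02 in adult lung. Without replicate 1 the list median was 1.72, Epcam 3.66 and Cldn4 4.30. This list's call was lost without reprogrammed lung replicate 3 (0.80, adjusted p = 0.106) or replicate 4 (0.71, adjusted p = 0.0588), and the median was -0.60 within slide 3.

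Of the measured adipocyte genes, 7 rose and 1 fell by both counts, with a median of 1.58 and adjusted p = 0.00723, and adjusted p = 0.506 with an estimated correlation. Fabp4, with a value on 2 of the reprogrammed lung arrays, rose by 5.11 (4.64 to 6.43 over its 3 probes), Aoc3, an amine oxidase of fat and vessel walls, by 3.73 and Adipoq by 3.36 (at least 9.04-fold). This call was lost over features above background on all arrays (0.61, adjusted p = 0.0927). Of the immediate-early and dissociation genes, 8 rose and 0 fell (9 and 0 when adjusted over the list alone), with a median of 0.87 and adjusted p = 0.0169, and adjusted p = 0.765 with an estimated correlation. Fos rose by 1.44, Nr4a1 by 1.40 and Hspa1a, a heat shock protein, by 1.32. This call was lost without reprogrammed lung replicate 3 (0.66, adjusted p = 0.0776) or replicate 4 (0.55, adjusted p = 0.194). Of the fatty acid and triglyceride synthesis genes, 6 fell and 2 rose (7 and 3 when adjusted over the list alone), with a median of -0.26 and adjusted p = 0.0411, and adjusted p = 0.643 with an estimated correlation. Scd2, a desaturase, stood at -1.68, Acss2, an acetyl-CoA synthetase, at -1.41 and Agpat2, an acyltransferase, at -1.33, while Thrsp rose by 1.96. This call was lost without reprogrammed lung replicate 1 (-0.39, adjusted p = 0.285), adult lung replicate 2 or 3, or reprogrammed mammary replicate 2, and with quantile normalization (adjusted p = 0.121), normexp (0.276), the authors' values (0.234), the replicate block (0.0522), array weights (0.184) and only the groups compared (0.132). Vim differed by 0.34 (adjusted p = 0.432).

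Lymphoid genes differed between the arrays of this comparison. The B cell list median was 2.85 on reprogrammed lung replicate 1, -3.59 on replicate 3 and -3.33 on replicate 4, against -2.49 to -2.35 on the adult lung arrays. The list was not called (median 0.16 with the mean also above 0 but the test pointing down, adjusted p = 0.918). T and NK cell genes had a median difference of -1.098 (adjusted p = 0.0724), and were called lower without reprogrammed lung replicate 1 (-2.50, adjusted p = 0.00475), adult mammary replicate 4 (adjusted p = 0.046) or reprogrammed mammary replicate 2 (0.0461). Neutrophil genes had a median of -0.22, and were called lower without that array (-1.49, adjusted p = 0.0098).

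**Figure D3:**
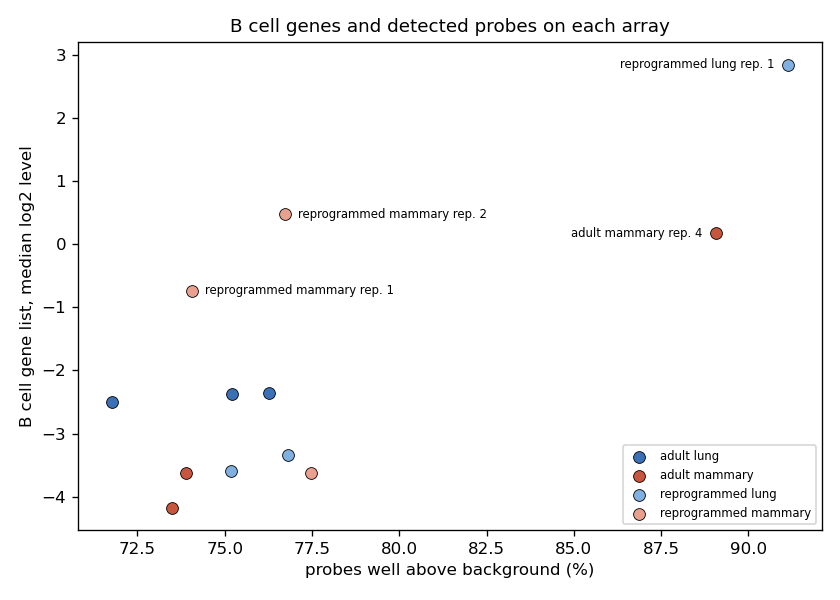
Median log2 level of the B cell genes (vertical) against the percent of probes well above background (horizontal) on each of the 12 arrays, coloured by group. Reprogrammed lung replicate 1 (91.1%, median 2.85) and adult mammary replicate 4 (89.1%, 0.17) lie apart on the right, and reprogrammed mammary replicate 2 (76.7%, 0.48) is high at a usual share of probes.

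In all, 3446 features rose and 2281 fell, 2482 and 1618 of them at least 2-fold. The share that rose was 60.2%, against 40.4% with normexp background correction, 47.5% with the authors' values and 50.7% with quantile normalization. Normexp moved the median of all features from 0.10 to -0.16. With normexp 3248 features passed, with the replicate block 3728 and with only the groups compared 3122. Within slides 1, 3 and 5, in this order, list medians were -4.08, -2.78 and -4.29 for alveolar type II genes, 6.92, 2.21 and 3.44 for milk genes, 3.76, 2.54 and 2.72 for hormone-sensing genes and -1.65, -1.49 and -1.92 for endothelial genes.

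The comparison of reprogrammed mammary with adult mammary asks the same for the cells named mammary. Few differences were found. The only feature past the threshold was a cDNA with no gene symbol, AK035950, 8.35-fold higher in reprogrammed mammary (log2 3.06 ± 0.24 SE, adjusted p = 0.00249, n = 3 per group). It was chosen for naming after its values were seen. At an unadjusted p under 0.05, limma gave 2457 features, against 1225 by chance.

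The lung markers named here did not pass the test. Sftpc differed from adult mammary by 0.75 (adjusted p = 0.653), Scgb1a1 by 0.17 (0.962), Ager by 0.07 (0.956), Nkx2-1, above background in neither group, by -0.32 (0.886) and Foxj1 by -1.60 (0.602). Among mammary markers, Csn2 differed by -1.19 (adjusted p = 0.894), Elf5 by -0.22 (0.938), Esr1 by 0.37 (0.86) and Krt14 by -1.20 (0.585). Epcam differed by 0.01 (adjusted p = 0.997), Vim by -0.16 (0.887) and Adipoq by 0.36 (0.896). A p that misses the threshold does not show that levels were equal, and the simulated data put recovery of 4-fold changes at 56 of 100 in this comparison. Those data held far more changed features than the 1 called here, which eases the adjusted threshold, so real recovery may be lower.

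Of the 33 lists, 0 were called by camera, 0 with an estimated correlation and 0 by fry. The lists with the smallest adjusted p, 0.15, were cell cycle genes (median -0.55), kidney tubule genes (0.38) and paralog group 6 to 13 Hox genes (0.35). Without adult mammary replicate 1, camera called 8 lists: cell cycle (-1.19, adjusted p = 2.69e-09), hormone-sensing (0.65), group 6 to 13 Hox (0.50), adipocyte (0.47), kidney tubule (0.47), interferon-response (0.44), matrix remodelling (0.34) and endothelial genes (0.23). Without adult mammary replicate 4, endothelial (-0.49, adjusted p = 0.00276), kidney tubule (0.74) and B cell genes were called, without reprogrammed mammary replicate 2 cell cycle (-0.97, adjusted p = 8.01e-05) and hormone-sensing genes (0.75), and without reprogrammed mammary replicate 3 interferon-response (0.50) and B cell genes. Camera also called cell cycle genes with quantile normalization (-0.60, adjusted p = 0.0457), normexp (-0.52, 0.000601), the authors' values (-0.62, 0.0127) and the slide as a fixed block (-0.66, 0.00505). It called hormone-sensing genes with the authors' values (0.32) and over features above background on all arrays (1.04), milk genes with the slide as a fixed block (0.97), and basal (-0.32) and group 6 to 13 Hox genes (0.39) with the replicate block. The cell cycle median was 0.85 within slide 2 and -2.13 within slide 4, and the milk median 1.71 and 0.40. B cell genes had a median difference of 1.12 (adjusted p = 0.371), with array medians of -3.63, -4.18 and 0.17 on adult mammary replicates 1, 2 and 4 and of -0.74, 0.48 and -3.63 on reprogrammed mammary replicates 1, 2 and 3. B cell genes were called higher without adult mammary replicate 4 (2.31, adjusted p = 0.0444) or reprogrammed mammary replicate 3 (2.03, adjusted p = 0.0471). The count of features was 0 with quantile normalization, normexp, the replicate block and the slide as a fixed block, and 394 with array weights. It was 19 without reprogrammed lung replicate 1, 10 without replicate 3 and 7 without replicate 4, 3 without adult mammary replicate 4, and 2 without adult mammary replicate 1 or reprogrammed mammary replicate 2 or 3.

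The comparison of the reprogrammed groups with each other asks whether the organ name separates them. Only 2 features passed, both higher in reprogrammed lung and both above background on its 3 arrays alone: AK037912, a cDNA with no gene symbol (at least 1.84-fold, log2 3.17 ± 0.28 SE, adjusted p = 0.0104, n = 2 and 3), and Olfr652, an odorant receptor (at least 1.89-fold, log2 2.77 ± 0.25 SE, adjusted p = 0.0104, n = 3 per group). The cDNA was chosen for naming after its values were seen. Olfr652 is 1 of 1013 odorant and pheromone receptor genes on the array. Their median level was -3.32, -4.55 and -5.57 on reprogrammed lung replicates 1, 3 and 4. It was -5.91, -5.41 and -5.75 on reprogrammed mammary replicates 1, 2 and 3. At an unadjusted p under 0.05, limma gave 2350 features, against 1225 by chance. Olfr652 was not called with quantile normalization, normexp or the authors' values, with a trend in limma's variance (adjusted p = 0.128), with the replicate block (0.1), with the slide as a fixed block (0.999) or with only the groups compared (0.466), nor without reprogrammed mammary replicate 1 (adjusted p = 0.065) or 2 (0.086).

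Markers of lung were not past the test. Nkx2-1, above background in neither group, differed by 0.76 (adjusted p = 0.692), Sftpc by 0.45 (0.804), Ager by -0.06 (0.96), Scgb1a1 by 0.59 (0.833) and Foxj1 by 1.69 (0.599). Mammary markers were not past it either: Csn2 differed by 0.18 (0.984), Esr1 by -0.82 (0.649), Elf5 by -0.83 (0.691) and Krt14 by -0.85 (0.722). Epcam differed by -1.14 (0.604), Vim by 0.58 (0.551) and Adipoq by -0.30 (0.907).

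Camera called 6 lists in which 0 single members passed over all features. All 6 had adjusted p = 0.98 with an estimated correlation, and fry called 0. Hormone-sensing luminal genes had a median of -1.30 (adjusted p = 3.05e-06), with 7 of 15 members lower when adjusted over the list alone, led by Stc2, a secreted glycoprotein (-2.76), Prom1, a luminal surface protein (-2.04), and Pgr, the progesterone receptor (-2.04). Calca, also in that list, differed the other way, by 2.58, without passing the test (adjusted p = 0.581). Pan-epithelial genes had a median of -0.99 (adjusted p = 4.31e-07), with Krt19 at -1.88 and Krt7 at -1.65. Cell cycle genes had a median of -0.57 (adjusted p = 0.00252), with Ccnb1, a mitotic cyclin, at -1.61 and Cdk1 at -1.33. Fibroblast genes had a median of -0.48 (adjusted p = 0.0307), with Col1a1 at -0.94. Endothelial genes had a median of 0.62 (adjusted p = 0.000271), with Sox17 at 0.86 and Egfl7 at 0.73, and paralog group 6 to 13 Hox genes 0.34 (adjusted p = 0.0307), with Hoxd13 at 1.12. In the last 5 of these lists 0 members passed when adjusted over the list alone.

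Without reprogrammed lung replicate 1, the array with the most probes above background, the medians were -0.21 for pan-epithelial (adjusted p = 0.05), -0.09 for fibroblast (0.952) and 0.17 for Hox genes (0.324), none of them called. The cell cycle call was lost without reprogrammed lung replicate 3 (-0.37, adjusted p = 0.102) or 4 (-0.34, 0.139) or reprogrammed mammary replicate 2 (-0.19, 0.326). The fibroblast call was also lost without reprogrammed lung replicate 3 or reprogrammed mammary replicate 3, and the Hox call without reprogrammed lung replicate 4 or reprogrammed mammary replicate 3. The fibroblast call was also lost with quantile normalization (adjusted p = 0.102), the authors' values (0.125), features above background on all arrays (0.0586) and the slide as a fixed block (0.1), and the Hox call with the replicate block (0.0513) and array weights (0.723). Within slide 5, medians were -0.37 for hormone-sensing, -0.25 for pan-epithelial, -2.18 for cell cycle, 0.48 for endothelial and 1.099 for fibroblast genes. B cell genes, with a median difference of 0.20 and a mean of 0.12 but a test pointing down, were called lower without reprogrammed lung replicate 1 (-1.90, adjusted p = 0.00726). Without reprogrammed lung replicate 4, 162 features passed, without replicate 3, 13, without reprogrammed mammary replicate 3, 5, and without reprogrammed mammary replicate 1 or 2, 0. The count was 4 without adult lung replicate 1, adult mammary replicate 4 or reprogrammed lung replicate 1.

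Each reprogrammed group was also set against the other adult group. Reprogrammed mammary differed widely from adult lung: 3646 features were higher and 2748 lower, 2392 and 2019 of them at least 2-fold. Sftpc stood at log2 -9.79 (n = 2 adult lung arrays), Nkx2-1 at -9.05 (at least 116-fold), Akap5 at -7.70 and Ager at -7.22, and Csn3 at 11.02 (at least 765-fold), Csn1s2a at 10.04 (at least 253-fold), Ptn at 8.20 (n = 2 reprogrammed mammary arrays) and Prlr at 7.33. Camera called 12 lists. Alveolar type II (median -4.11), type I (-2.55) and airway secretory genes (-4.30) were also called with an estimated correlation. Milk (5.37, or 3.79 with 7 members at their bound), hormone-sensing (4.50), basal (1.40), pan-epithelial (1.86), adipocyte (1.18), ribosomal protein (0.97) and paralog group 6 to 13 Hox genes (0.26) were higher, and ciliated (-1.16) and endothelial genes (-2.46) lower, with adjusted p = 0.115 to 0.508 with an estimated correlation. The adipocyte call was lost without reprogrammed mammary replicate 1 (adjusted p = 0.056), with normexp (0.0887), with the slide as a fixed block (0.0501) and over features above background on all arrays (0.186), which ended the Hox call too (0.276). The share that was higher was 57.0%, against 42.6% with normexp, which moved the median of all features from 0.04 to -0.24. Within slide 5 the medians were -3.15 for alveolar type II, 5.17 for milk and -2.61 for endothelial genes. With the slide as a fixed block 2437 features passed.

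Reprogrammed lung differed from adult mammary at 7 features, all higher in reprogrammed lung, against 2890 at an unadjusted p under 0.05 in limma. They were AK035950 (log2 3.43), AK037912 (at least 1.97-fold, 2.94), Olfr652 (at least 2.04-fold, 2.90), Tecta, a protein of the inner ear's tectorial membrane (at least 2.23-fold, 2.64), Trim12c (2.01) and Trim12a (1.28), tripartite motif proteins, and Ankrd12, an ankyrin repeat protein (1.44). They were named after their values were seen, and adjusted p ran from 0.000815 to 0.0498. Camera called 8 lists in which 0 members passed over all features, with adjusted p = 0.903 with an estimated correlation for each, and fry called 0. Medians were -1.09 for pan-epithelial (Cldn4 at -1.75), -1.07 for cell cycle (Cdk1 at -2.03), -0.43 for hormone-sensing and -0.30 for basal genes (Krt15 at -2.75). They were 0.72 for paralog group 6 to 13 and 0.49 for group 1 to 5 Hox genes, 0.78 for kidney tubule genes and 0.55 for endothelial genes (Egfl7 at 1.15). Adjusted over the list alone, 1 endothelial, 1 kidney, 2 group 1 to 5 and 1 group 6 to 13 Hox gene were higher.

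In that comparison, the pan-epithelial median was -0.26 without reprogrammed lung replicate 1 (-1.76 on that array, 0.77 to 0.84 on the adult mammary arrays), and the cell cycle median -1.82 without adult mammary replicate 1 and -0.56 without replicate 4. The hormone-sensing, basal, kidney and group 1 to 5 Hox calls were lost without reprogrammed lung replicate 1 (adjusted p = 0.239, 0.385, 0.177 and 0.111), and the endothelial call without adult mammary replicate 4 (median 0.16, adjusted p = 0.468). The hormone-sensing call was also lost without adult mammary replicate 1, the basal call without adult mammary replicate 1 or 2 or reprogrammed lung replicate 4, the kidney call without adult mammary replicate 2 or reprogrammed lung replicate 3, and the group 1 to 5 Hox call without adult mammary replicate 2 or 4 or reprogrammed lung replicate 4. Over features above background on all arrays the basal, kidney and group 1 to 5 Hox calls were lost (adjusted p = 0.174 for each), with array weights the hormone-sensing (0.0671), basal (0.521) and group 1 to 5 Hox calls (0.163), and with the slide as a fixed block the hormone-sensing (0.345) and basal calls (0.18). The basal call was lost with quantile normalization (0.0733), and the kidney call with normexp (0.075) and the replicate block (0.116). Within slide 1, medians were -0.05 for pan-epithelial, 0.14 for hormone-sensing, 0.11 for basal, -2.10 for cell cycle and 0.46 for endothelial genes. The count ran from 2 (without adult lung replicate 3, adult mammary replicate 2 or reprogrammed mammary replicate 2) to 328 (without reprogrammed lung replicate 4). It was 18 without adult mammary replicate 4, 19 without reprogrammed lung replicate 3, 3 without adult mammary replicate 1 or reprogrammed mammary replicate 1, and 4 without adult lung replicate 1 or reprogrammed mammary replicate 3.

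The last comparison asks whether the change from adult to reprogrammed cells differed between the organ names. It did, at 1816 features with a more positive change in lung and 1321 with a more negative one, 1639 and 1220 of them at least 2-fold (n = 3 per group, and 2 adult lung arrays for Sftpc). By arithmetic, this difference equals that between the reprogrammed groups less that between the adult groups, each as lung minus mammary. The first had 2 features called and the second 6978, so the values below largely restate the adult organ difference with its sign turned. The most negative of the named genes were those of lung epithelium, with Chia1 at log2 -10.10 ± 0.67 SE (adjusted p = 6.52e-05), Sftpc at -10.09 ± 0.72 SE (adjusted p = 0.000129), Scgb1a1 at -9.58, Sftpa1 at -8.21 and Nkx2-1 at -7.97. On the positive side stood Calca at 10.74 ± 1.89 SE (adjusted p = 0.00591), Wfdc18 at 10.68, Alox12e, a lipoxygenase (9.37, adjusted p = 0.0221), Csn1s1 (8.82, adjusted p = 0.0298) and Csn3 (8.65). Another tested probe gave -6.21 for Chia1, -9.06 for Sftpa1, 5.45 for Calca and 12.03 for Wfdc18. The sizes for Chia1, Nkx2-1, Calca, Alox12e and Csn1s1 rest on at least 1 group in which no array was above background. Calca had a group mean of -6.38 in adult lung, 1.78 in adult mammary, -2.63 ± 3.34 (SD, n = 3) in reprogrammed lung and -5.21 in reprogrammed mammary, where only 1 array was above background. Leaving out 1 array moved Calca to between 8.96 and 12.27, Alox12e to between 7.06 and 10.70, Csn1s1 to between 6.87 and 10.31 and Sftpa1 to between -9.21 and -6.74. Alox12e was not past the threshold without adult lung replicate 2 or 3 or reprogrammed mammary replicate 3, and Csn1s1 not without any 1 of the adult lung or reprogrammed mammary arrays or without adult mammary replicate 2 or 4. Alox12e was also lost with quantile normalization (8.10, adjusted p = 0.072), normexp (4.95, 0.0964), the replicate block (0.0821) and the slide as a fixed block (8.66, 0.0814), and Csn1s1 with normexp (4.00, 0.324), the authors' values (5.91, 0.0903), the replicate block (0.0781) and the slide as a fixed block (7.65, 0.0793). The count of features ran from 1792 without adult lung replicate 2 to 5252 without reprogrammed lung replicate 1. The share with a more positive change was 57.9%, against 47.2% with quantile normalization, 44.0% with the authors' values and 36.4% with normexp, which moved the median of all features from 0.07 to -0.20.

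With 1 feature called in reprogrammed mammary against adult mammary, at most 1 shared change could be counted, so this count says little about shared changes. That feature, AK035950, also rose in reprogrammed lung against adult lung, where chance gave 0.141 shared rises. Fisher's exact test, which counted calls in either direction, gave p = 0.234. The shared count was 34 without reprogrammed lung replicate 1 and adult mammary replicate 4 together and 130 with array weights. Across features, which are not independent replicates, the changes correlated at r = 0.0870.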

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

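The tests on the brightest lung genes and on random lists matched for level were chosen after the result was seen. The others in this part were set before their own result was seen.

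The change from adult to reprogrammed cells differed between the organ names at 3137 features, in limma's test of that difference itself. Since the reprogrammed groups differed from each other at 2 features and the adult groups at 6978, this largely restates the adult organ difference. It is not a separate result. Lung epithelial lists changed more negatively in lung, with medians of log2 -4.37 for alveolar type II (adjusted p = 3.85e-10), -2.95 for alveolar type I (5.95e-16) and -3.94 for airway secretory genes (2.86e-08), all of them also called with an estimated correlation. The medians were -0.70 for ciliated (adjusted p = 0.0312) and -1.82 for endothelial genes (4.8e-08). They were 1.70 for hormone-sensing luminal (adjusted p = 0.0175), 2.90 for milk and alveolar luminal (0.00106), 1.69 for basal (0.00329), 1.41 for pan-epithelial (0.00614), 1.04 for group 6 to 13 Hox (0.000567), 0.70 for immediate-early (0.0431) and 1.03 for ribosomal protein genes (3e-15). With an estimated correlation these last 9 lists were not called, with adjusted p = 0.094 to 0.78. Members past the threshold numbered 12 of 16 alveolar type II, 11 of 15 alveolar type I, 11 of 16 endothelial and 25 of 37 ribosomal protein genes, and 0 of the immediate-early genes. The ciliated call was lost without adult mammary replicate 2 (-0.51, adjusted p = 0.108) or reprogrammed lung replicate 3 (-0.39, 0.057), the hormone-sensing call without adult mammary replicate 1 (1.67, 0.0571) or reprogrammed lung replicate 4 (1.63, 0.0612), and the pan-epithelial call without reprogrammed lung replicate 3 (0.97, 0.0822) or 4 (0.90, 0.0517). The immediate-early call was lost without adult lung replicate 1 or 3, adult mammary replicate 1, reprogrammed lung replicate 3 or 4, or reprogrammed mammary replicate 1 (0.48 to 0.73, adjusted p = 0.0539 to 0.228). The group 6 to 13 Hox median was 0.41 without reprogrammed lung replicate 1, and the basal median 1.09 without adult lung replicate 1. Over features above background on all arrays the milk (1.38, adjusted p = 0.589), hormone-sensing (0.28), group 6 to 13 Hox (0.203) and ciliated calls (0.0544) were lost, and with the replicate block the hormone-sensing (0.0637) and immediate-early calls (0.0838).

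Among the marker genes, the difference was log2 -7.97 for Nkx2-1, -10.09 for Sftpc, -7.36 for Ager, -9.58 for Scgb1a1, 4.29 for Esr1 and 2.85 for Elf5, with adjusted p from 3.01e-05 (Ager) to 0.0483 (Elf5). The other 6 marker genes did not pass. Without reprogrammed lung replicate 1, B cell (-3.21, adjusted p = 0.0462), T and NK cell (-2.84, 0.00618) and neutrophil genes (-0.97, 0.042) were called more negative as well.

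The reprogrammed lung arrays lay beside the mammary arrays, which is the pattern behind these values. The tables argue against normalization or background correction, since the highest mean position under quantile normalization, normexp and the authors' values was 0.197. Adult lung RNA mixed in met its first test, since the share of adult lung signal over 2146 genes was 17.2%, 2.36% and 4.08% on the reprogrammed lung arrays against at most 1.18% on reprogrammed mammary (smallest gap 1.18 points), but it would bring its most abundant transcripts, and over the 30 brightest lung genes the share was at most 0.140%. Residual lung expression may be present, with a camera p of 0.00103 for the genes highest in adult lung, without replicate 1. Their median change of 0.17 then lay at percentile 97.1 of random lists matched for level (95% of them between 0.01 and 0.17). With all arrays it was 0.61 and lay above that range, at percentile 99.96 (95% between 0.345 and 0.539). Since the 2 settings disagree, a raised signal of dim probes and residual expression cannot be told apart. Cells of mammary origin among those collected, and the organ names themselves, stay open and untested, since no label tells donor from host cells.

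Other splits of the arrays were counted for each comparison. With 6 arrays there are 10 splits, too few for a share under 0.05. The real split gave 6978 features for adult lung against adult mammary (highest other 0), 5727 for reprogrammed lung against adult lung (highest other 1), 6394 for reprogrammed mammary against adult lung (highest other 0), 1 for reprogrammed mammary against adult mammary (highest other 0) and 2 for the reprogrammed groups (highest other 1). For reprogrammed lung against adult mammary the real split gave 7, and 4 of the 10 splits gave as many or more. The highest, 85, set reprogrammed lung replicate 1 with adult mammary replicates 2 and 4, which points to a structure of the arrays other than their groups. For the organ difference, 1 of 100 assignments, the real one, gave as many as 3137 (highest other 2675). They shuffled all 4 groups, so cannot isolate this difference. For shared changes 1 of 100 assignments, the real one, gave as many as 1 (highest other 0), which decides nothing. Chance gave 0.141 shared rises, and Fisher's exact p over calls in either direction was 0.234.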

How the results depend on the processing

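The fit without reprogrammed lung replicate 1 and adult mammary replicate 4 together, the array weights and the raw median signal in normexp were chosen after seeing the data. Changes within a slide carry no test, yet 292 of them for list medians and 161 for named genes count as unchanged below. There, called items kept their direction, and uncalled items count as unchanged whatever their direction. Of the list medians called in the main values, 1498 alternatives kept direction and, where tested, the call. Another 98 kept direction only and 8 reversed. Of those not called, 4005 stayed so, 192 were called in the same direction and 7 were called in the opposite one. Of the alternatives for named genes that were called, 1695 kept direction and, where tested, the call, 71 kept direction only and 0 reversed. Of those not called, 773 stayed so and 14 were called.

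For the counts, the cause was not tested unless named. Quantile normalization gave 0 features for reprogrammed mammary against adult mammary (1 list), 0 for the reprogrammed groups and 0 shared. Normexp background correction gave 3248 for reprogrammed lung against adult lung, 0 for reprogrammed mammary against adult mammary (1 list), 0 for the reprogrammed groups, 0 for reprogrammed lung against adult mammary, 1444 for the organ difference, 0 shared, and a reprogrammed mammary position of 0.0507. The authors' series matrix values gave 6 for reprogrammed mammary against adult mammary (2 lists), 0 for the reprogrammed groups, 3 for reprogrammed lung against adult mammary, 4 shared and a position of 0.0575. No filter on dim probes gave 3 for reprogrammed lung against adult mammary. Features well above background on all arrays, which are fewer, gave 6 for reprogrammed mammary against adult mammary (1 list), 0 for the reprogrammed groups, 4 for reprogrammed lung against adult mammary and 3 shared. The mean of a gene's probes gave 2 for reprogrammed mammary against adult mammary and 2 shared. eBayes with trend gave 0 for the reprogrammed groups and 2 for reprogrammed lung against adult mammary.

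The replicate block, which leaves fewer degrees of freedom, gave 3728 for reprogrammed lung against adult lung, 0 for reprogrammed mammary against adult mammary (2 lists), 0 for the reprogrammed groups, 0 for reprogrammed lung against adult mammary, 1137 for the organ difference and 0 shared. The slide as a fixed block, which does so too, gave 2702 for adult lung against adult mammary, 0 for reprogrammed mammary against adult mammary (2 lists), 0 for the reprogrammed groups (12 lists), 0 for reprogrammed lung against adult mammary, 2437 for reprogrammed mammary against adult lung, 1167 for the organ difference and 0 shared. The slide as a random block, with a correlation of -0.026, moved no count by over 1.5 times, and camera was not run with it. Only the groups of the comparison, with 6 arrays in the fit, gave 3122 for reprogrammed lung against adult lung, 10765 for reprogrammed mammary against adult lung, and 0 for reprogrammed mammary against adult mammary, the reprogrammed groups, reprogrammed lung against adult mammary and shared changes.

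Without reprogrammed lung replicate 1 and adult mammary replicate 4 together, 82 features passed for reprogrammed mammary against adult mammary (4 lists), 11 for the reprogrammed groups, 24 for reprogrammed lung against adult mammary (2 lists), 5713 for the organ difference and 34 shared, with a reprogrammed mammary position of 0.124. Array weights gave 394 for reprogrammed mammary against adult mammary, 24 for the reprogrammed groups, 2 for reprogrammed lung against adult mammary, 12494 for reprogrammed mammary against adult lung, 5874 for the organ difference and 130 shared. The weight was 0.123 for reprogrammed lung replicate 1, 0.392 for reprogrammed lung replicate 4 and 0.501 for adult mammary replicate 4. The lung and mammary gene lists only gave a reprogrammed mammary position of -0.00765.

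Leaving out each of the 12 arrays in turn gave 4730 to 9407 features for adult lung against adult mammary, 1 to 19 for reprogrammed mammary against adult mammary (0 to 8 lists), 0 to 162 for the reprogrammed groups, 2 to 328 for reprogrammed lung against adult mammary, 1792 to 5252 for the organ difference, 1 to 9 shared, and a reprogrammed mammary position of 0.0569 to 0.130. Where 2 arrays of a group were left, they were assumed to vary like the other groups.

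With an estimated inter-gene correlation the number of lists was 3 for adult lung against adult mammary, 3 for reprogrammed lung against adult lung, 3 for reprogrammed mammary against adult lung, 3 for the organ difference, and 0 for the reprogrammed groups and for reprogrammed lung against adult mammary. With fry it was 7 for the organ difference and 0 for the reprogrammed groups and for reprogrammed lung against adult mammary.

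Some list medians reversed, with the cause not tested. Group 6 to 13 Hox genes in adult lung against adult mammary stood at 0.29 with normexp, 0.046 over features above background on all arrays and 0.40 within slide 1, and at -0.10 with normexp in reprogrammed mammary against adult lung. With the slide as a fixed block, macrophage genes stood at -0.68 for the reprogrammed groups and -0.59 for reprogrammed lung against adult mammary, and T and NK cell genes at -1.20 for the latter. Leaving out arrays, endothelial genes ran from -0.49 to 0.23 in reprogrammed mammary against adult mammary, B cell genes from -1.90 to 1.31 for the reprogrammed groups (-1.90 without reprogrammed lung replicate 1 and adult mammary replicate 4 together), and milk genes from -0.65 without reprogrammed lung replicate 3 to 0.85 without replicate 1 in reprogrammed lung against adult mammary. Within slides, pan-epithelial genes stood at -0.60 (reprogrammed lung against adult lung, slide 3), fibroblast genes at 1.099 (reprogrammed groups, slide 5), and hormone-sensing and basal genes at 0.14 and 0.11 (reprogrammed lung against adult mammary, slide 1). Signal over background limits dim probes: the median signal of the negative controls was 18 to 23, and 20731 of the 24504 features tested were above background on every array.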

Other observations

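The tests of a slide effect on the 2 arrays with more probes above background, of a lower epithelial share alone and of endothelial cells were chosen after the result was seen, and the others in this part were planned.

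Lymphoid genes varied between arrays of the same group. The B cell list median was log2 2.85 on reprogrammed lung replicate 1, 0.48 on reprogrammed mammary replicate 2, 0.17 on adult mammary replicate 4 and -0.74 on reprogrammed mammary replicate 1, and -4.18 to -2.35 on the other 8 arrays. On the arrays with a positive median, Cd79b, a B cell receptor chain, stood at 5.11, 1.52 and 0.92 (0.36 to 0.87 in adult lung). The T and NK cell list median there was 0.13, -0.23 and -0.58. It was -0.91 to -0.79 in adult lung and -3.46 to -2.35 elsewhere. Among members, Cd3g stood at 1.96, 3.22 and 2.09 (0.33 to 0.73 in adult lung) and Nkg7 at 2.20, 2.35 and -0.74 (0.13 to 1.89). The neutrophil list median on reprogrammed lung replicate 1 was 3.26 above the mean of the 4 groups.

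Adult mammary replicate 4 and reprogrammed lung replicate 1 had more probes above background than the other 10 arrays. The tables argue against a slide effect, since the other arrays of their slides exceeded the highest share on the remaining slides by at most 0.673 points. Cells of another type are a candidate explanation, as B cell genes rose on both arrays above the other arrays of their group (6.77 and 3.93) by at least 2.62 more than 1013 odorant and pheromone receptor genes did, and the labels state no cell sort that would remove lymphocytes. Reprogrammed mammary replicate 2 had like T cell gene levels with 76.7% of probes above background, and the receptor genes, 83.7% of them above background on reprogrammed lung replicate 1, are not lymphocyte genes, so such cells would not account for the whole pattern. A raised signal of dim probes stays open, since the receptor median lay 1.22 above every other array on reprogrammed lung replicate 1 but was -0.366 against the highest other array on adult mammary replicate 4 (SD 0.591 over the other arrays).

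On the adult lung arrays endothelial genes were high and pan-epithelial genes low. If both organs held the same mix of other cells, a lower epithelial share alone would raise these cell types alike. The endothelial median exceeded the higher of the fibroblast and macrophage medians by at least 1.81 on each adult lung array. The mix may differ between the organs and was not measured, so this test cannot decide on a lower epithelial share. A slide effect was argued against, as the median was higher in adult lung by at least 1.49 within each slide that holds it. Endothelial cells among the adult lung cells may contribute and stay open: 4 of 5 endothelial markers were above background and higher than in adult mammary (Pecam1 1.48, Cdh5 2.74, Kdr 2.79 and Tie1 2.37), while Vwf differed by 0.26 (adjusted p = 0.563). The labels give washes and low-speed centrifugation and no sort against endothelial cells, and a biological difference between the organs was not tested apart from this.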
